A study of Mus musculus with 6 samples.

How the data were processed

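MicroRNA (miRNA) levels were measured on one-colour Agilent miRNA arrays in 6 samples, 3 sorts of Fr. B/C cells from adult bone marrow and 3 from fetal liver, each on 1 array. Total RNA was isolated with TRIzol, and 100 ng per sample was dephosphorylated and end-labelled with Cy3 by a ligase, per the labels' protocols. Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, and the deposited scanner tables give the intensity of every spot on a linear scale. The main column, the processed signal, is an intensity from which Feature Extraction had subtracted the background within each array, per the file headers, so that it can be negative, and it was not yet normalised between arrays. The authors also deposited a table of log2 values per spot. Its 6 columns share 1 distribution, from 4.66 to 15.79 with medians of 5.24, which is the mark of quantile normalisation, and the 2 copies of the table held the same value in 100 percent of cells. Its rank correlation with the processed signal lay between 0.963 and 0.994 per array, and the background correction behind it is not given in the sources used here, so it served as an alternative only. The other spot values are flags of 0 or 1, such as the call of a spot as well above background, set by Feature Extraction per the file headers.

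The array holds 1672 probes for 567 mouse miRNAs, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. Spots of a probe were averaged without those marked as outliers. A probe counted as well above background on an array where more than 50 percent of its spots were. Each array was scaled by its 75th percentile over the 82 probes well above background on all 6 arrays, since most probes did not pass that mark. The scaled signal then got 1 common floor of 16.5, which is 4.04 on the log2 scale and the median over arrays of the 5th percentile of scaled signals well above background. Values were then put on the log2 scale. A miRNA can be well above background on an array and still lie at the floor. Values at the floor have no order, and a fold against them is not exact. It can also overstate a fall on fetal liver replicate 2, where the lowest signal well above background was 58.7 before scaling by 1.81. A rise can be overstated there too, since signals not well above background could lie above the floor on that array. Let-7g*, miR-294 and miR-329, well above background on no array, had 6.38, 6.25 and 6.17 (log2) there and lay at the floor on every other array. Each miRNA was represented by its brightest probe. The second probe of each called miRNA was compared with it, and of 29 calls 27 had a second probe with the same direction, 0 had the opposite direction and 2 had a second probe at the floor on all arrays.

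A miRNA was tested if it was well above background on all 3 arrays of at least 1 group, which held for 135 miRNAs (23.8 percent). Fetal liver was compared with bone marrow in limma 3.58.1 under R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, and a miRNA is called at an adjusted p under 0.05. All differences are fetal liver minus bone marrow on the log2 scale. Lists of miRNAs were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 8 lists with at least 3 tested members, and again with camera at an estimated correlation and with fry, which asks whether the members of a list move on balance in 1 direction. The per-array mean over the let-7 list was compared with a two-sided exact permutation test. Figures were drawn with matplotlib 3.10.9.

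Groups, tests, the alternatives, 17 lists of miRNAs and the rule for naming miRNAs were fixed before the data were examined. The lists were the let-7 guide arms, the let-7 passenger arms, the miR-99/100 and miR-125 miRNAs that share clusters with let-7, the cluster from miR-17 to miR-92a with its paralogs, the miR-15/16, miR-29 and miR-23/24/27 families, lymphoid and B cell regulators, the Dlk1-Dio3 and Sfmbt2 clusters, the miR-290 to miR-295 and miR-302 clusters, miRNAs hosted by H19 and Igf2, and markers of erythroid, myeloid, hepatocyte, stem or progenitor, and stromal cells. Named were all tested let-7 guide miRNAs, the 10 largest rises and 10 largest falls among calls whose groups did not overlap, up to 3 members of each other list with the smallest p, and the members of the lists of other cell types. Alternatives covered other scalings, normexp background correction with an offset of 50, other rules for probes, floors and filters, the deposited table, the replicate number as a block, an intensity trend, array weights, and leaving out each array. A looser filter of 2 of 3 arrays, and a fit without fetal liver replicate 2 over the same tested miRNAs, were chosen after seeing the data. The permutation test of the let-7d level minus the let-7a level was also chosen then.

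On data simulated for the comparison over 135 miRNAs (20 simulations), 3.8 percent of unchanged miRNAs were called, and 68 percent of miRNAs changed by 1 and 98 percent of those changed by 2 on the log2 scale were called in the right direction. A let-7 list shifted by 1.5 was called in 100 percent of simulations and other lists in 1.4 percent of tests. The simulated log2 noise was independent between miRNAs and had 1 SD in both tissues. In the data camera estimated correlations from -0.14 to 0.61 within the lists, with 0.52 for the let-7 guides. These rates therefore do not show how often calls and list tests err on the data. The number of arrays, 3 per group, limits the precision. The replicates are separate sorts from different animals, each on 1 array, so the p-values measure the spread between sorts and between arrays together. The median SD of the tested miRNAs was 0.161 in bone marrow and 0.488 in fetal liver, while limma used 1 variance per miRNA for both tissues. Replicate numbers in the labels do not name a shared animal, litter or day. All 6 arrays lay on 1 slide with 1 scan, bone marrow in slide row 1 and fetal liver in slide row 2, so slide row and tissue cannot be told apart. Probe positions are those in the scanner tables, on mouse build mm9 (NCBI37), and an annotation of that build was not used here. Control spots and 10 viral miRNAs were left out of the comparison.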

Results

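MicroRNAs were measured in B cell progenitors of BALB/c mice at 2 stages of life. The cells were Fr. B/C, the pro-B stage of the Hardy scheme, in which immunoglobulin heavy chain genes are rearranged. They were sorted from adult bone marrow (3 sorts, each from 3 female mice) and from fetal liver at day 16 of gestation (3 sorts, each from the embryos of 1 litter, 8 on average). The study concerns Lin28b, an RNA-binding protein of fetal progenitors that blocks the maturation of let-7 miRNAs, and the comparison asks which miRNAs, let-7 first, differ between fetal and adult pro-B cells.

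The arrays differed in signal over background. Between 18.4 and 23.7 percent of mouse miRNA spots were well above background on 5 arrays, and 7.02 percent on fetal liver replicate 2, where the SD of the negative control spots was 12.1 against 2.65 to 4.13 on the other arrays. Scale factors ran from 0.614 for bone marrow replicate 2 to 1.81 for fetal liver replicate 2. Across the tested miRNAs, which are not independent replicates, Pearson's r was 0.969 to 0.987 between bone marrow arrays, 0.853 to 0.927 between fetal liver arrays and 0.745 to 0.878 between arrays of different tissues. On all 3 arrays of a tissue, 135 miRNAs were well above background in bone marrow and 53 in fetal liver, and these 53 all belonged to the 135. Without fetal liver replicate 2, the fetal liver number was 119, of which 10 were outside the bone marrow set. The 135 tested miRNAs were thus those of bone marrow, and miRNAs found in fetal liver alone had 0 entries among them.

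The let-7 family was the main group that differed. The let-7 guide miRNAs, which repress growth and fetal-stage genes such as Lin28b itself, were lower in fetal liver for all 9 members tested, and 7 of them fell past the threshold. Let-7b fell 17.3-fold, from 8.57 ± 0.14 to 4.46 ± 0.72 (log2 scaled signal, mean ± SD, n = 3 arrays each, limma with Benjamini-Hochberg adjustment, adjusted p = 7.21e-04), and it was at the floor on 2 of 3 fetal liver arrays, so that its fold depends on the floor. Let-7c fell 10.2-fold (log2 difference -3.35 ± 0.57 SE), let-7i 7.73-fold (-2.95 ± 0.34) and let-7d 6.72-fold (-2.75 ± 0.21). Let-7c and let-7i were well above background on 2 of 3 fetal liver arrays, so that their folds are not exact. Without fetal liver replicate 2 they differed by -2.94 and -2.63. Let-7g fell 3.15-fold and let-7f 2.53-fold. MiR-98 fell by 1.53 ± 0.20 SE (log2), but was well above background on 1 fetal liver array and at the floor on another, so that its fold is not exact. Adjusted p-values of these 7 from limma with Benjamini-Hochberg adjustment lay between 5.76e-04 and 0.00747. Let-7a, at 10.65 ± 0.11 in bone marrow and 9.86 ± 0.31 in fetal liver, was lower on all 3 fetal liver arrays than on any bone marrow array and missed the threshold (log2 difference -0.79 ± 0.23 SE, limma with Benjamini-Hochberg adjusted p = 0.0514). Let-7e, close to the floor in both tissues, had 4.92 ± 0.12 in bone marrow and 4.28 ± 0.42 in fetal liver (limma, Benjamini-Hochberg adjusted p = 0.148).

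**Figure D1:**
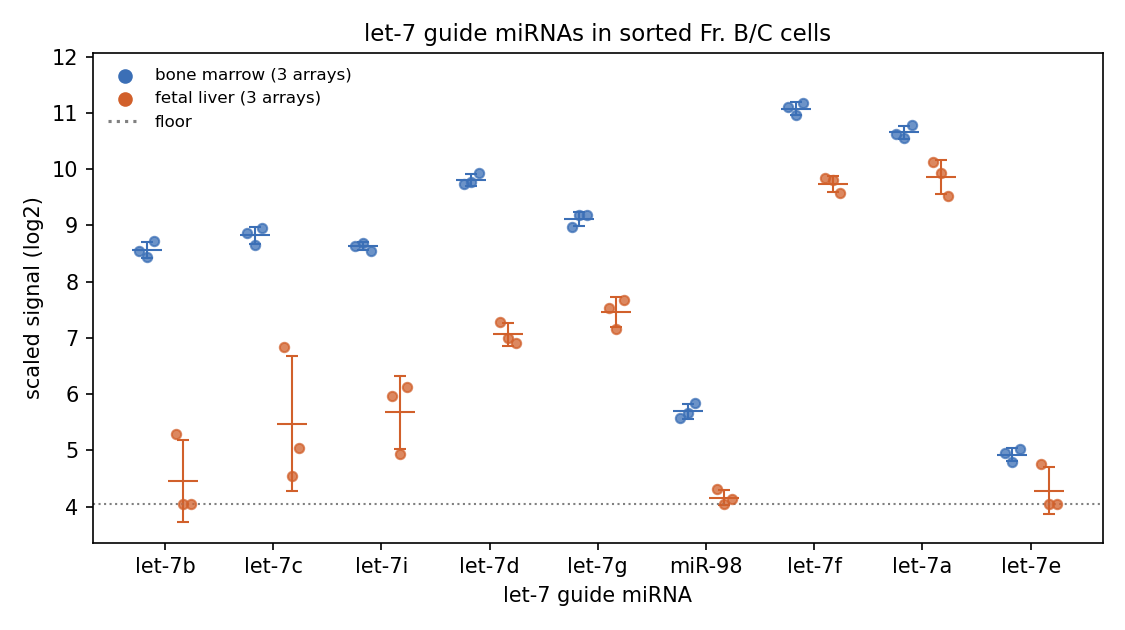
Log2 scaled signal (y axis) of the 9 let-7 guide miRNAs (x axis, ordered by their difference) on 3 bone marrow and 3 fetal liver arrays. Points are arrays, dashes are means, bars are SDs and the dotted line is the floor of 4.04. All fetal liver points lie below the bone marrow points of the same miRNA, from let-7b (difference -4.11) to let-7e (-0.64).

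The list of let-7 guides had a median difference of -1.66, and 9 of 9 members passed when adjusted over the list alone. Camera gave an adjusted p of 4.41e-09 at the preset correlation (limma, Benjamini-Hochberg), adjusted p = 0.277 with an estimated correlation, and fry gave an adjusted p of 0.00266. The mean level over the 9 guides was 8.59 ± 0.09 in bone marrow and 6.46 ± 0.38 in fetal liver (n = 3 each), a difference of -2.12. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The members fell unequally. The let-7a, let-7f and let-7d probes map within 1 stretch of chromosome 13 (mm9, from 48631447 for let-7d to 48633627 for let-7a), and the let-7d level minus the let-7a level went from -0.84 ± 0.06 in bone marrow to -2.79 ± 0.16 in fetal liver (n = 3 each, exact permutation p = 0.1). This pair was chosen after the values were seen. The let-7b and let-7c probes map to chromosome 15 (mm9, 85537758 to 85537776 and 85537049 to 85537067). All 9 members stayed lower in fetal liver under each of 4 other scalings, among which let-7a was called without scaling (adjusted p = 0.00583), with quantile normalisation (0.0355) and in the deposited table (0.00636), each by limma with Benjamini-Hochberg adjustment, in a range of 0.00583 to 0.245 over all alternatives. Over the alternatives the differences ran from -5.57 to -1.93 for let-7b, -4.03 to -1.86 for let-7c, -3.71 to -1.66 for let-7i, -3.51 to -2.13 for let-7d, -2.42 to -1.22 for let-7g and -2.10 to -1.29 for let-7f. With 1 array left out let-7c ran from -4.03 to -2.94, and with normexp background correction let-7c had -1.86 and let-7i -1.66. Let-7e was called lower in 3 alternatives (limma, Benjamini-Hochberg adjusted p from 0.0127). The call of let-7c ended without bone marrow replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0699, range over alternatives 1.71e-11 to 0.184), and those of let-7c and let-7i ended without a filter on detection (0.184 and 0.0531). The call of miR-98 ended with normexp (difference -0.30, limma, Benjamini-Hochberg adjusted p = 0.997) and at a floor of 1 (-2.88, adjusted p = 0.188).

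The passenger arms of let-7, cut from the same precursors, gave no call in limma and 0 at an unadjusted p under 0.05. Of 7 on the array, 2 were tested, let-7b* with a difference of 1.09 ± 0.69 SE and let-7d* with 0.03 ± 0.73. Let-7b* ran from 0.43 to 1.75 when 1 array was left out, and was called higher without fetal liver replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0306). Let-7d* had a negative difference under each of the 4 other scalings. Of the miRNAs that share clusters with let-7, miR-125b-5p, a regulator of haematopoietic stem cells, and miR-99a fell. MiR-125b-5p was not well above background on any fetal liver array, and its level in bone marrow (5.94 ± 0.21) was at least 1.88-fold higher, taking each fetal array at the lowest signal well above background (limma, Benjamini-Hochberg adjusted p = 0.00216). Its difference went from -1.81 to -0.29 with normexp, where its call ended (limma, Benjamini-Hochberg adjusted p = 0.997). MiR-99a was at the floor on all 3 fetal liver arrays (difference -0.88, limma, Benjamini-Hochberg adjusted p = 0.0136), so near background that no bound on its fold is given, and its call ended without any 1 of the bone marrow arrays (adjusted p up to 0.0729) and with scaling over all mouse probes. The call of miR-99a also ended with normexp, all probes averaged, total gene signal, a replicate block and a doubled floor, where the difference was 0. With all probes averaged miR-99a differed by -0.44 and miR-125b-5p by -0.90. The second probe of miR-125b-5p was at the floor on all arrays. MiR-125a-5p had a difference of 0.10 ± 0.26 SE and a negative one under the 4 other scalings. With 2 of 3 members called, also when adjusted over the list alone, the list had an adjusted p of 0.0805 by camera (limma, Benjamini-Hochberg), 0.630 with an estimated correlation and 0.00436 by fry.

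Over all 135 tested miRNAs, limma with Benjamini-Hochberg adjustment called 29, of which 14 were higher and 15 lower in fetal liver. The groups did not overlap for any of the 29. At an unadjusted p under 0.05 there were 44. Among all tested miRNAs 55 (40.7 percent) had groups that did not overlap, against 10 percent by chance for 3 against 3. The median difference of the tested miRNAs was 0.25, and the other scalings shifted it by -0.76 (none), -0.32 (75th percentile over all mouse probes), -0.23 (quantile) and -0.16 (deposited table). The split of higher and lower calls moved with it, to 4 and 20 without scaling, 6 and 15 over all mouse probes, 9 and 17 with quantile normalisation and 11 and 18 in the deposited table. Of the 29 calls 18 were shared by these 4 scalings, 14 lower and 4 higher (miR-714, miR-451, miR-296-5p and miR-721). Leaving out 1 bone marrow array cut the count to 19 (replicate 1), 16 (replicate 2) or 12 (replicate 3), and 11 calls, 9 lower and 2 higher, held in all 6 fits that leave out an array. With normexp 10 of the 29 calls stayed, those of let-7b, let-7c, let-7d, let-7f, let-7g, let-7i, miR-146a, miR-34a, miR-451 and miR-714. Without a filter on detection 11 stayed, and those of let-7c, let-7i, miR-223, miR-34a, miR-451 and miR-714 were among the lost ones.

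**Figure D2:**
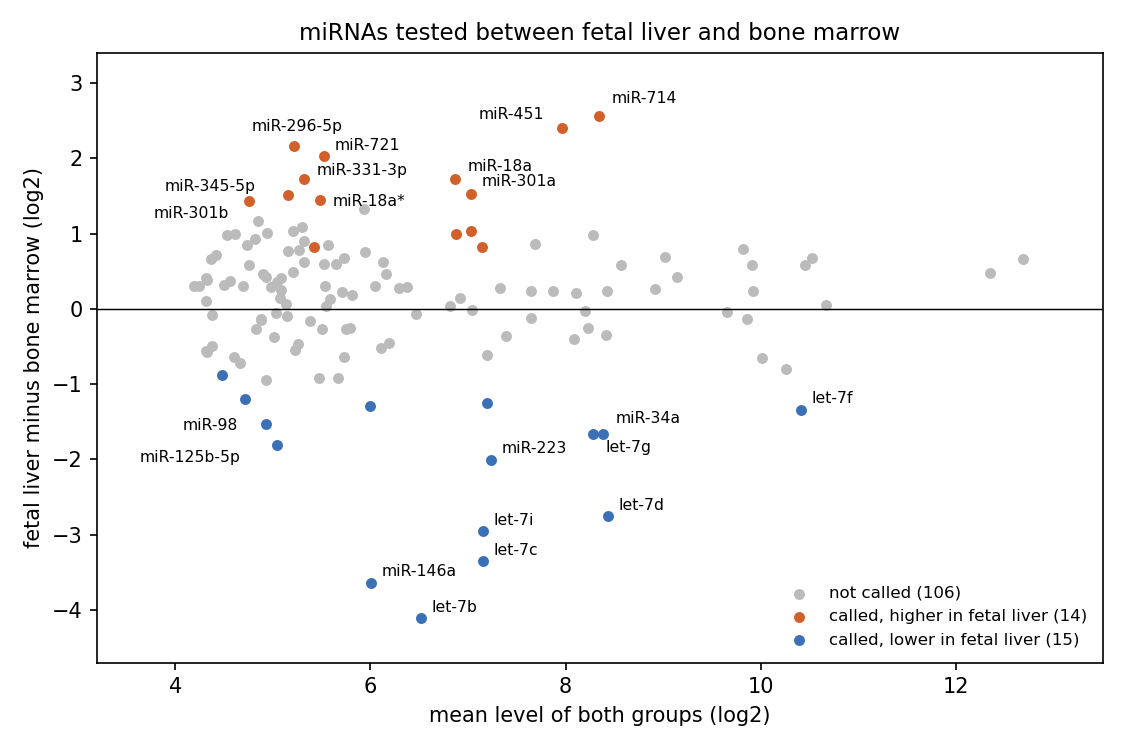
Difference between fetal liver and bone marrow (log2, y axis) against the mean level of both groups (log2, x axis) for the 135 tested miRNAs, 1 point each. The 14 called higher and 15 called lower are coloured. Let-7b, miR-146a, let-7c, let-7i and let-7d hold the lowest values and miR-714 and miR-451 the highest, at 2.57 and 2.41, while the higher calls other than miR-714, miR-451, miR-296-5p and miR-721 were lost under at least 1 other scaling.

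Outside let-7, miR-146a, a brake on NF-kB signalling in lymphoid and myeloid cells, had the largest fall, 12.4-fold (7.82 ± 0.48 in bone marrow, 4.18 ± 0.25 in fetal liver, n = 3 each, limma, Benjamini-Hochberg adjusted p = 5.76e-04), and lay at the floor on 2 of 3 fetal liver arrays and well above background on 1, so that its fold depends on the floor. Its second probe had a smaller difference of -1.43, and with normexp it had -1.51. MiR-223, abundant in granulocytes and monocytes and well above background on 2 of 3 fetal liver arrays, fell 4.01-fold (8.24 ± 0.48 to 6.24 ± 0.48, limma, Benjamini-Hochberg adjusted p = 0.00786). These were the 2 tested members of the myeloid list, and both also passed when adjusted over the list alone. The other 3 members, miR-511, miR-146b and miR-146b*, were at the floor on all 3 bone marrow arrays and not tested, and miR-511 differed the other way, by 0.89 (0.29 over fetal liver replicates 1 and 3). MiR-511 was well above background on 2 bone marrow arrays and 1 fetal liver array, so that the size of its difference is not exact. The call of miR-223 ended without bone marrow replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0525, range over alternatives 6.79e-05 to 0.160). Over the alternatives the difference of miR-146a ran from -6.33 to -1.51 and that of miR-223 from -2.77 to -1.12.

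Of 12 tested lymphoid and B cell regulators, 2 fell and 1 rose, with the same counts when adjusted over the list alone, and the list as a whole did not pass (median -0.24, camera in limma with Benjamini-Hochberg adjusted p = 0.469). The list median ran from -0.85 to 0.14 over the alternatives and from -0.44 to -0.0455 with 1 array left out, and the list was called in none of them. MiR-34a, which blocks the pro-B to pre-B transition through Foxp1, fell 3.16-fold (9.21 ± 0.04 to 7.55 ± 0.70, limma, Benjamini-Hochberg adjusted p = 0.0170). MiR-181a, a modulator of lymphocyte receptor signalling, fell 2.38-fold (limma, Benjamini-Hochberg adjusted p = 0.0252), and miR-181d rose 1.77-fold (limma, Benjamini-Hochberg adjusted p = 0.0374). MiR-181a and miR-181d were well above background on 2 of 3 fetal liver arrays. On the second probes miR-181a differed by -1.20 and miR-181d by 0.10. MiR-181b (0.14) and miR-181c (-0.57), named after their values were seen, were not called. In the same list miR-150, which targets Myb and was well above background on 1 fetal liver array, differed by -0.92 ± 0.57 SE and miR-155 by 0.28 ± 0.21, both not called and both named outside the rule, after their values were seen. Their second probes had the opposite sign, with 0.29 for miR-150 and -0.22 for miR-155. MiR-29a, well above background on 2 of 3 fetal liver arrays, fell 2.45-fold (limma, Benjamini-Hochberg adjusted p = 0.0102). MiR-29b, the other tested member of the miR-29 family, differed by -0.72 ± 0.34 SE and was not called, so that 1 of 2 passed, also when adjusted over the list alone. With 1 array left out miR-29b ran from -0.99 to -0.41. The call of miR-34a ended without any 1 of the bone marrow arrays or fetal liver replicate 2 (limma, Benjamini-Hochberg adjusted p up to 0.0979), that of miR-29a without any 1 of the bone marrow arrays (up to 0.0564), and that of miR-181a without bone marrow replicate 2 or 3 or fetal liver replicate 2 (up to 0.129). The call of miR-181d was lost under all 4 other scalings and in 5 of 6 fits that leave out an array (limma, Benjamini-Hochberg adjusted p up to 0.157 there).

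The cluster from miR-17 to miR-92a and its paralogs, which promote survival of B cell progenitors, had 14 tested members with a median difference of 0.59. MiR-18a rose 3.31-fold (6.01 ± 0.19 in bone marrow, 7.73 ± 0.64 in fetal liver, n = 3 each, limma, Benjamini-Hochberg adjusted p = 0.0130) and its partner arm miR-18a* 2.73-fold (limma, Benjamini-Hochberg adjusted p = 0.0316). They were the 2 members called, also when adjusted over the list alone. Without fetal liver replicate 2, miR-18a differed by 1.86 and miR-18a* by 1.03, both still called by limma. MiR-20a differed by 0.80 ± 0.25 SE (limma, Benjamini-Hochberg adjusted p = 0.0659) and was called in 2 alternatives, over miRNAs well above background on all 6 arrays and with an intensity trend. Its difference ran from 0.0334 to 0.95 over the alternatives (limma, Benjamini-Hochberg adjusted p up to 0.981) and from 0.49 to 0.95 with 1 array left out. Camera called the list higher (limma, Benjamini-Hochberg adjusted p = 0.0180), with adjusted p = 0.630 with an estimated correlation and 0.0759 by fry. The list call also ended without scaling, where the median was -0.11 while camera still pointed up (adjusted p = 0.106), over all mouse probes (0.150) and without fetal liver replicate 3 (0.279), each in limma with Benjamini-Hochberg adjustment, in a range of 1.22e-07 to 0.630 over all alternatives. MiR-18a* was called under none of the 4 other scalings and miR-18a under 3 of 4, and both calls ended without bone marrow replicate 2 or 3 (limma, Benjamini-Hochberg adjusted p up to 0.154 for miR-18a* and 0.0950 for miR-18a).

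On the main probe of each miRNA, the largest rises were those of miR-714 and miR-451. MiR-714 rose 5.93-fold (7.06 ± 0.38 to 9.63 ± 0.77, n = 3 each, limma, Benjamini-Hochberg adjusted p = 0.00672), and the table gives no position for its probe. With all probes averaged its difference was 1.48, against 2.57 on the main probe, and lay below those of miR-451 (2.38), miR-721 (2.05), miR-296-5p (1.99) and miR-18a (1.73). MiR-451, an erythroid miRNA (probe on chromosome 11, mm9, 77886688 to 77886709), rose 5.30-fold (6.75 ± 0.43 to 9.16 ± 0.36, limma, Benjamini-Hochberg adjusted p = 0.00252). MiR-296-5p rose 4.49-fold from values at the floor on 2 of 3 bone marrow arrays, and miR-721 rose 4.08-fold from 4.51 ± 0.08, also close to the floor (limma, Benjamini-Hochberg adjusted p = 0.00216 and 0.00672). MiR-331-3p rose 3.30-fold, miR-301a 2.88-fold, miR-345-5p 2.86-fold and miR-301b 2.70-fold, the last from the floor on all 3 bone marrow arrays (limma, Benjamini-Hochberg adjusted p between 0.00838 and 0.0318). These 4 calls were each lost under at least 2 of the 4 other scalings and in at least 1 fit that leaves out an array. Without fetal liver replicate 2 the differences were 1.16 for miR-331-3p, 1.12 for miR-345-5p, 1.66 for miR-301a and 1.72 for miR-301b, all still called by limma. The calls of miR-714 and miR-721 ended without bone marrow replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0564 and 0.0525), and those of miR-451 and miR-296-5p held in all 6 fits that leave out an array. Yet miR-296-5p, miR-345-5p and miR-301b had no probe well above background on all 3 fetal liver arrays, so that their folds are not exact. With normexp the calls of miR-296-5p (difference from 2.17 to 0.42), miR-721 (2.03 to 0.51), miR-331-3p (1.72 to 0.37), miR-345-5p (1.52 to 0.29) and miR-301b (1.43 to 0.16) ended (limma, Benjamini-Hochberg adjusted p = 0.997 each). The normexp offset by itself shrinks differences of dim miRNAs, and its share in these changes was not tested.

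**Figure D3:**
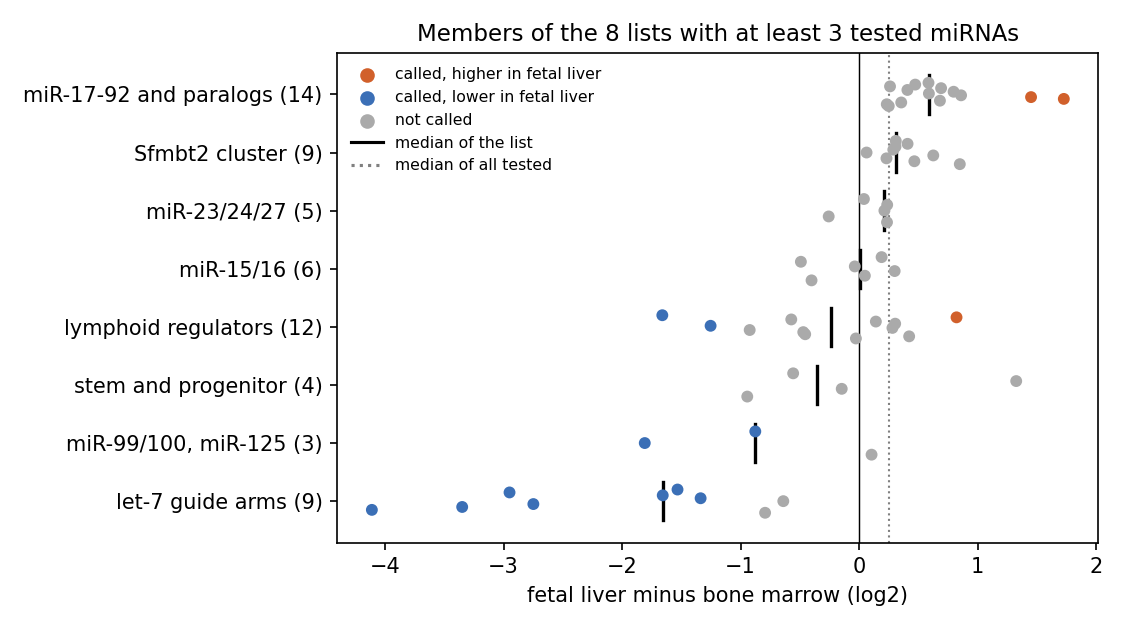
Difference between fetal liver and bone marrow (log2, x axis) of each tested member of the 8 lists with at least 3 tested miRNAs (y axis, number tested in brackets). Points are miRNAs, black lines are list medians and the dotted line is the median of all tested miRNAs, 0.25. The let-7 guides have a median of -1.66 and the list of the miR-17 cluster and its paralogs 0.59, which turned to -0.11 without scaling.

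Several other families gave no call. None of 6 tested members of the miR-15/16 family, 5 of the miR-23/24/27 clusters and 9 of the Sfmbt2 cluster was called, over all miRNAs or adjusted over the list alone, and the list tests gave adjusted p of 0.615, 0.886 and 0.507 (camera in limma, Benjamini-Hochberg). At an unadjusted p under 0.05 in limma there were 0, 0 and 1. In these lists miR-15a differed by -0.40 ± 0.24 SE, miR-23b by -0.26 ± 0.20 and miR-466e-3p by 0.85 ± 0.26, the last called in 2 alternatives, with a doubled floor and with array weights. The Dlk1-Dio3 cluster, an imprinted cluster with placental and neural expression, had 1 tested miRNA of 70 on the array, miR-494 (-0.92 ± 0.57 SE, not called, -1.33 to -0.31 with 1 array left out), and 66 of the 70 were well above background on no array. The miR-290 to miR-295 and miR-302 clusters of early embryo cells had 1 tested of 22, miR-290-3p, at the floor on all 3 bone marrow arrays (0.99 ± 0.48 SE, not called). Still, miR-290-3p was well above background on all 3 bone marrow arrays and on 1 fetal liver array, so that the size of its difference is not exact. It was called without fetal liver replicate 3 (1.43, limma, Benjamini-Hochberg adjusted p = 0.0245) and with array weights (0.0356), and had 0.53 without fetal liver replicate 2. The 4 miRNAs hosted by H19 and Igf2 were not tested, and 3 of them were well above background on no array.

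Markers of other cells in marrow and fetal liver moved in different directions. Both tested members of the myeloid list, miR-146a and miR-223, fell, as given above. Whether these falls lie in the pro-B cells or in other cells of the sorts was not tested. In the erythroid list miR-451 rose, and miR-144 was at the floor on all 6 arrays. MiR-486 was well above background on 2 arrays of each tissue but at the floor in bone marrow, and differed by 1.46 ± 0.38 SE. MiR-486 was not among the tested miRNAs and was called when 2 of 3 arrays sufficed (limma, Benjamini-Hochberg adjusted p = 0.0434), but not without fetal liver replicate 2 (1.29, limma, Benjamini-Hochberg adjusted p = 0.0968). Of the hepatocyte markers, miR-122 was well above background on 1 array, fetal liver replicate 1, and miR-192 and miR-194 on none. All 11 stromal miRNAs, among them miR-143, miR-145, miR-199b, miR-214 and miR-218, were well above background on no array. Of 4 tested stem or progenitor markers none was called by limma and 1 had an unadjusted p under 0.05 (camera in limma, Benjamini-Hochberg adjusted p = 0.615), with miR-130a at 1.33 ± 0.38 SE (limma, Benjamini-Hochberg adjusted p = 0.0513), miR-10a at -0.94 ± 0.42, miR-196b at -0.56 ± 0.24 and miR-126-3p at -0.15 ± 0.40. MiR-10a and miR-196b were well above background on no fetal liver array, and at the floor on 2 and 3 of them, so that these differences lie close to background and their sizes are not exact. MiR-130a alone passed when adjusted over the list alone. Without fetal liver replicate 2, miR-130a (1.68) and miR-10a (-1.47) were called (limma, Benjamini-Hochberg adjusted p = 0.00731 and 0.0231), and the sign of miR-126-3p turned (0.18, not called). Both were also called with array weights, miR-10a without scaling and in the deposited table, and miR-196b at a floor of 1 and in the deposited table.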

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

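A probe of the viral miRNA mghv-miR-M1-2, from a mouse herpesvirus and outside the comparison of mouse miRNAs, was well above background on 5 of 6 arrays, which is why it is listed here. Its processed signal, not scaled between arrays, was 20.7 ± 0.967 in bone marrow and 24.5 ± 7.61 in fetal liver (mean ± SD, n = 3 each), and the medians of the negative control spots lay between 1.00 and 13.2. No explanation was tested.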

How the results depend on the processing

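The results rest on 3 arrays per tissue, of which fetal liver replicate 2 had the lowest signal over background, and no setting separates tissue from slide row, since a slide or scan block could not be fitted with 1 slide, 1 scan and 1 tissue per row. None of the 29 called miRNAs had the opposite sign in any of 22 refits that tested it, and 5 (all lower) were called in every one. The call count stayed within 1.5 times of 29 in 17 of 23 alternatives. It was 10 (2 higher, 8 lower) with normexp, 12 (3 and 9) without a filter on detection, 18 (13 and 5) over miRNAs well above background on all 6 arrays, and 12 to 41 when 1 array was left out. The numbers of the sorts did not pair them (correlations of deviations 0.17, -0.12 and -0.24 for same-numbered arrays, and not every array correlated best with its own number), and a replicate block gave 23 calls. Let-7 guides were called lower by camera in every alternative except the estimated correlation (median -1.66, adjusted p = 0.277), and the difference of their mean level ranged from -2.78 to -1.27. The fetal liver detection count was 53 to 119 when 1 array was left out and 119 in the added fit without replicate 2. The median of the miR-17 cluster and its paralogs was 0.27 over all mouse probes, -0.11 without scaling, 0.64 over miRNAs well above background on all 6 arrays, 0.49 with array weights and 0.59 with the estimated correlation or fry, without a call in these, and 0.35 to 0.76 with an array left out. The miR-99/100 and miR-125 list was called at a floor of 1 (median -2.70), with the added filter of 2 of 3 arrays (-0.88), with fry (-0.88) and without fetal liver replicate 2 (-0.98, also in the added fit), and had -0.98 to -0.82 with an array left out. The miR-23/24/27 test changed direction, never called, over all mouse probes (-0.11), without scaling (-0.55), with total gene signal (0.12), over all 6 arrays (0.21), with array weights (0.20), without bone marrow replicate 2 (0.0620), without fetal liver replicate 2 (0.15, also in the added fit) and without fetal liver replicate 3 (0.0647), and the median was 0.0620 to 0.22 with an array left out. The miR-15/16 test changed direction without a filter (0) and the stem or progenitor test with normexp (-0.0864) and with a doubled floor (0.0735), all without a call. Among lists with few tested members, the medians for miR-29 were -1.58 without scaling, -0.34 with normexp, -1.68 at a floor of 1 and 0 without a filter. For the myeloid list they were -3.44 without scaling, -1.32 with normexp, -2.15 with mean probes, -4.17 at a floor of 1, -2.39 with a doubled floor, 0 without a filter, -2.14 in the deposited table, -2.004 with 2 of 3 arrays and -3.04 to -1.73 with an array left out. For the erythroid list they were 1.64 without scaling, 1.76 with normexp, 1.46 without a filter, 1.93 with 2 of 3 arrays and 1.82 to 2.65 with an array left out. Without a filter the Dlk1-Dio3 and early embryo cluster medians were 0, and with normexp the latter was 0.0833. The sign turned for some uncalled miRNAs. Let-7d* had -0.46 over all mouse probes, -0.77 without scaling, -0.33 with quantile normalisation, -0.25 at a floor of 1, -0.0512 in the deposited table, -0.0350 with array weights, -0.80 in the added fit and -0.80 to 0.70 with an array left out. MiR-125a-5p had -0.22, -0.56 and -0.33 under these scalings, -0.0713 with normexp, -0.46 at a floor of 1, -0.28 in the deposited table, -0.17 in the added fit and -0.17 to 0.20 with an array left out. Over all mouse probes and without scaling, miR-23a had -0.0880 and -0.53 and miR-24 -0.11 and -0.55. Without scaling miR-467a* had -0.14 and miR-669a -0.34, and miR-669a had -0.12 with quantile normalisation and -0.0236 in the deposited table. MiR-126-3p had 0.15 with a doubled floor, 0.18 without fetal liver replicate 2 (also in the added fit) and -0.61 to 0.18 with an array left out. MiR-15b* had -0.11 with normexp and -0.0152 in the deposited table. Fewer or more tested miRNAs go with the filters, and fewer samples with arrays left out. The normexp offset shrinks the differences of dim miRNAs. Otherwise the cause was not tested. Of 1006 values of 47 named miRNAs under the alternatives, 823 kept their direction and side of the threshold, 121 lost and 32 gained the call, and 30 turned sign. Under the 2 added alternatives, chosen after seeing the data, the counts were 35 with 2 of 3 arrays and 28 without fetal liver replicate 2.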

Other observations

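Several calls fell outside the naming rule and were named after their values were seen. The paralogs miR-103 and miR-107 rose 1.99-fold and 1.76-fold in fetal liver (limma, Benjamini-Hochberg adjusted p = 0.0173 and 0.0362), miR-652 rose 2.04-fold (0.0101) and miR-221, which restrains Kit in progenitors, fell with a bound of at least 1.21-fold higher in bone marrow (0.00786). The calls of miR-103, miR-107 and miR-652 were lost under 2 of the 4 other scalings, and held in 3, 1 and 4 of the 6 fits that leave out an array. The call of miR-221 ended with normexp, at a floor of 1 and with a doubled floor. MiR-301a and miR-301b, both called, share a seed with miR-130a (1.33 ± 0.38 SE, limma, Benjamini-Hochberg adjusted p = 0.0513) and miR-130b (0.24 ± 0.22), neither of which was called in the main fit, and this family was not tested as a list. With the looser filter of 2 of 3 arrays, 23 miRNAs were added and 4 of them called, all higher in fetal liver (miR-712, miR-363, miR-106b* and miR-486), and 0 called lower by limma (0 at an unadjusted p under 0.05). All of the added miRNAs lay at the floor on bone marrow replicates 2 and 3. A fall could thus hardly be seen, and the shared direction of these calls carries no information.

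All tests below except those on splits of the arrays were chosen after the result was seen. The splits covered the call count and only those lists that camera had called, let-7 and the miR-17 cluster with its paralogs. The 6 arrays make 10 splits into 3 and 3, so no share under 0.05 can be reached. Every split but the real one mixes the tissues within its groups, so that a tissue difference adds to the spread there and lowers the call count. The tested miRNAs were also filtered on the real groups. The splits therefore do not show what chance alone would give. The real split called 29 miRNAs, and it was the 1 split of the 10 with as many, since the other splits called at most 0 in limma (up to 15 at an unadjusted p under 0.05). For the absolute median difference of the let-7 list the real split gave 1.66 against at most 0.79 in the others (1 of 10 as large), and for the list of the miR-17 cluster and its paralogs 0.59 against at most 0.42 (1 of 10 as large).

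The let-7 miRNAs fell unequally, let-7a and let-7f by less than let-7d. The positions given with their probes lie in the same stretch of chromosome 13. A probe does not tell from which locus its mature miRNA comes, and a contribution of other loci was not tested. The tables argue against the floor as the cause for let-7a and let-7f, since the lower of their bone marrow levels lay 6.61 above it and let-7d fell by 2.75. They also argue against a single faulty probe, since on the second probes the difference of let-7d minus that of let-7a was -2.30 (-1.96 on the main probes). For let-7e and miR-98 the floor may account for the smaller fall, since the higher of their bone marrow levels lay 1.66 above it. Cross-hybridisation between near-identical members stays open, because the level of let-7e in bone marrow (4.92, against a floor of 4.04) speaks of the let-7e probe only. Also open, and untested, is the hypothesis that a block on maturation acts unequally on the members.

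MiR-451 rose in fetal liver, a site of red cell formation at this age. Scaling does not account for it, since the difference without scaling was 1.64 (limma, Benjamini-Hochberg adjusted p = 0.0165, with a range of 3.31e-04 to 0.0596 over the alternatives), nor does fetal liver replicate 2, without which it was 2.36. Erythroid RNA in the sorted cells is a candidate explanation, from a marker list fixed beforehand, since miR-486 also differed by 1.46 ± 0.38 SE (1.29 and not called without fetal liver replicate 2), although miR-144 was at the floor on all 6 arrays and a sort for B lineage cells would remove erythroid cells. MiR-451 was well above background on all bone marrow arrays too, and miR-486 on 2 arrays of each tissue. Higher miR-451 in fetal pro-B cells themselves stays open and was not tested.

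MiR-714 and miR-721 rose, and both belong to a numbered series of mouse miRNAs, some of which were later reassigned to fragments of structural RNAs. MiR-712 of this series, outside the main fit, was called under the looser filter (1.47, limma, Benjamini-Hochberg adjusted p = 0.00262) and without fetal liver replicate 2 (1.63, 0.00229). The high background of fetal liver replicate 2 does not account for the rise, since without that array the lower of both differences was 1.62 (limma, Benjamini-Hochberg adjusted p up to 0.0208, with ranges over the alternatives of 1.26e-04 to 0.157 for miR-714 and 0.00105 to 0.997 for miR-721). The other 8 members numbered from 680 to 730 in the main fit, without miR-712 and none of them called there, had a median difference of 0.67, above that of 96.95 percent of 10000 random lists matched on level, but without fetal liver replicate 2 the median was 0.43, above 90.21 percent. A shift shared by such RNAs thus stays open, as does whether it would lie in the cells, in RNA quality or in labelling, none of which was tested.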
